A study of Homo sapiens with 8 samples.

How the data were processed

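The 8 libraries were of polysome-associated RNA pulled down with anti-GFP beads from MDA231-BrM2 cells, purified with a column kit and made into TruSeq RNA v2 libraries, per the labels' protocols. Sequencing was on an Illumina HiSeq instrument, per the series design. TopHat2, HTSeq, DESeq2 and the genome build hg19 are named without versions, per the submitters' processing notes. The annotation, counting mode and strand setting are not stated in the sources used here, nor is the species of the astrocytes.

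The deposited table holds whole-number counts per gene for 57445 genes and 5 HTSeq counter entries in each of the 8 columns, although its name calls the values normalized. The values were checked for their unit. All were whole, every integer from 1 to 60 occurred in every column, and median-of-ratios factors ran from 0.889 to 1.13, where values already divided by such factors would lie near 1. The deposited values were therefore treated as unnormalized counts, which used the test set out in advance for that case. All 8 columns were mapped to a group by their titles, and no column was left unmapped.

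Of the totals in the table, alignments that were not unique made up 14.2% to 26.1%, the highest share being in library 1 of the control coculture. Ambiguous reads made up 2.63% to 3.20%, reads outside features 3.77% to 4.53%, and unaligned reads 4.72% to 5.45%. The counter entries were left out of the tests. Gene counts ranged from 38219702 to 48997555 per library, and the 10 highest genes held 3.39% to 3.84% of them. A floor of 3 counts and exact 95% intervals for ratios of reads were computed for genes near the floor. The spread between replicates exceeded counting error in each group, with a chi-square per degree of freedom of 13.6, 22.0, 32.6 and 4.22 in control cells alone, control cocultures, hairpin 1 and hairpin 2.

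Counts were tested in R 4.3.3 with the quasi-likelihood method of edgeR 4.0.16. Genes with a mean count of at least 10 over the 8 libraries were kept, 15806 in all, and scaled by TMM factors, which ran from 0.975 to 1.03. The design held the 4 groups only, with all libraries in 1 fit, because each group has 2. The common biological coefficient of variation was 7.66% and the prior degrees of freedom were 4.73. P-values were adjusted by the Benjamini-Hochberg method over the tested genes, with a threshold of 0.05. Contrasts were the control coculture minus control cells alone, each Cx43 hairpin minus the control coculture, the mean of both hairpins minus the control coculture (called depletion), and hairpin 2 minus hairpin 1. A contrast of the depleted cocultures minus control cells alone was added after the data were examined. CPM were computed with the TMM-scaled library sizes.

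The groups, contrasts, tests, filters, gene lists, rule for named genes and most of the alternatives were chosen before the data were examined. The 35 lists were interferon-stimulated genes, interferon-gamma-inducible genes, MHC class I and antigen processing, TNF and NF-kB targets, cytosolic DNA and RNA sensing, interferon ligands and receptors, connexins and pannexins, protocadherins and cadherins, brain metastasis genes, S phase, G2 and M phase, apoptosis and survival, p53 targets, hypoxia and glycolysis, unfolded protein response and ATF4 targets, cholesterol synthesis, oxidative phosphorylation, cytosolic ribosomal proteins, mitochondrially encoded genes, replication-dependent histones, immediate-early genes, TGF-beta targets and EMT, YAP and TEAD targets, Notch targets, metallothioneins and oxidative stress, heat shock proteins, matrix metalloproteases and invasion, receptor ligands and growth factors, and breast carcinoma line markers. The rest were markers of astrocytes, fibroblasts, neurons, microglia and macrophages, oligodendrocyte lineage and endothelium. The lists share some members. Each list with at least 5 tested members was tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over lists within a contrast. An estimated correlation and fry were run beside it. Members were counted at 0.05 over all genes and adjusted over the list alone.

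Named genes were GJA1 in every comparison, and in each contrast the 6 largest rises and the 6 largest falls among called genes. These needed a group mean of at least 50 counts in a compared group, no overlap between replicates, and a symbol that was not that of a clone, antisense, open reading frame, small RNA or pseudogene entry. For each list described, up to 4 members with the smallest p in that contrast could be named. Examples from lists kept their call without each library unless the text says otherwise. PCDH7 and members of the sensing list could be named anywhere. Some genes that this rule selects are not reported here. IFIT1 in the plot of levels, and CXCL5, CXCL6, CCL2, SMAD7, SKIL, CDKN2B, CHAC1, ADM2, COL3A1, FN1, DYNC1H1, GFAP, NTRK2, SOX9, SLC1A3, SOX2, GPM6B, RGS4, C4BPB, SPOCD1, LINC00707, CXCL10 and CTD-2328D6.1 where named outside this rule, were chosen after their values were seen.

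Correlations between contrasts that share control libraries were set beside 20 simulations of unchanged groups sharing the same libraries. The edgeR step was tested on simulated data for the 6 contrasts, with 200 of 15806 genes changed. It recovered 56.5% to 69.5% of genes changed 1.5-fold, 75.4% to 91.7% of those changed 2-fold and 92.2% to 100% of those changed 4-fold. False calls were 5.78% to 10.3% of calls, above the nominal rate. Genes were drawn independently in both kinds of simulation, so neither holds deviations shared across genes, such as trends with transcript length. Transcript lengths were taken from GENCODE 29 on GRCh38 by gene identifier, since no hg19 annotation was used here, and 97.6% of the identifiers of tested genes matched. Of the tested genes 83.7% had a coding transcript length. No coordinates are given.

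Alternatives were no filter, a filter at a mean of 50, DESeq2 1.42.0, limma on log2 values with pseudocounts of 0.5, 1 and 5, quantile normalization with limma, median-of-ratios factors, library size only, robust empirical Bayes, a fold minimum of 1.5, only the compared groups in the fit, a replicate block, and each library left out in turn. Without a library the remaining library of its group was assumed to vary like the other groups. Permutation of samples between groups was not run, since groups of 2 give too few arrangements.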

Results

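Ribosome-associated RNA was sequenced from MDA231-BrM2, a brain-metastatic derivative of the MDA-MB-231 breast cancer line, with and without astrocytes. Translating ribosome affinity purification (TRAP) was used, in which anti-GFP beads pull down the tagged polysomes of the carcinoma cells from a mixed lysate. The 8 libraries fell into 4 groups of 2. Cells with a control hairpin were grown alone or with astrocytes, and cells with either of 2 hairpins against connexin 43 (Cx43, the gap junction protein encoded by GJA1) were grown with astrocytes. Cocultures held 1 astrocyte per carcinoma cell and lasted 24 h. No Cx43-depleted cells without astrocytes were part of the design.

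Reads counted in genes came to 42752003 and 48997555 in the libraries of control cells alone and to 39135339 and 38219702 in the control cocultures. They came to 42682395 and 40290379 with Cx43 hairpin 1, and to 41344009 and 43736498 with Cx43 hairpin 2. Levels are given as CPM, computed from the deposited counts and scaled library totals, as mean ± SD over 2 libraries, and changes as log2 fold changes. At this depth 3 counts in a library corresponded to 0.0624 to 0.0805 CPM, a floor that, like every interval here, covers counting error only. All p-values rest on 2 libraries per group, which the series design calls independent replicates.

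GJA1 (ENSG00000152661.7), the targeted gene, was measured first in every library. Its level was 51.1 and 46.3 CPM in control cells alone and 65.9 and 64.7 CPM in control cocultures. It was 27.8 CPM in both hairpin 1 libraries, and 31.7 and 33.8 CPM in the hairpin 2 libraries. Against the control coculture GJA1 fell by 1.23 with hairpin 1 (SE 0.074, adjusted p = 1.86e-05) and by 1.00 with hairpin 2 (SE 0.073, adjusted p = 8.15e-05). Over both hairpins its log2 change was -1.11, which left 0.462 of the control level. The difference between the hairpins in GJA1 did not pass the test (0.24, adjusted p = 0.705). GJA1 was also higher in the control coculture than in control cells alone (0.42, SE 0.072, adjusted p = 0.00665). That call ended without library 2 of the control cells alone (0.34, adjusted p = 0.0621) and without library 1 of the control coculture (0.41, adjusted p = 0.0512).

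**Figure D1:**
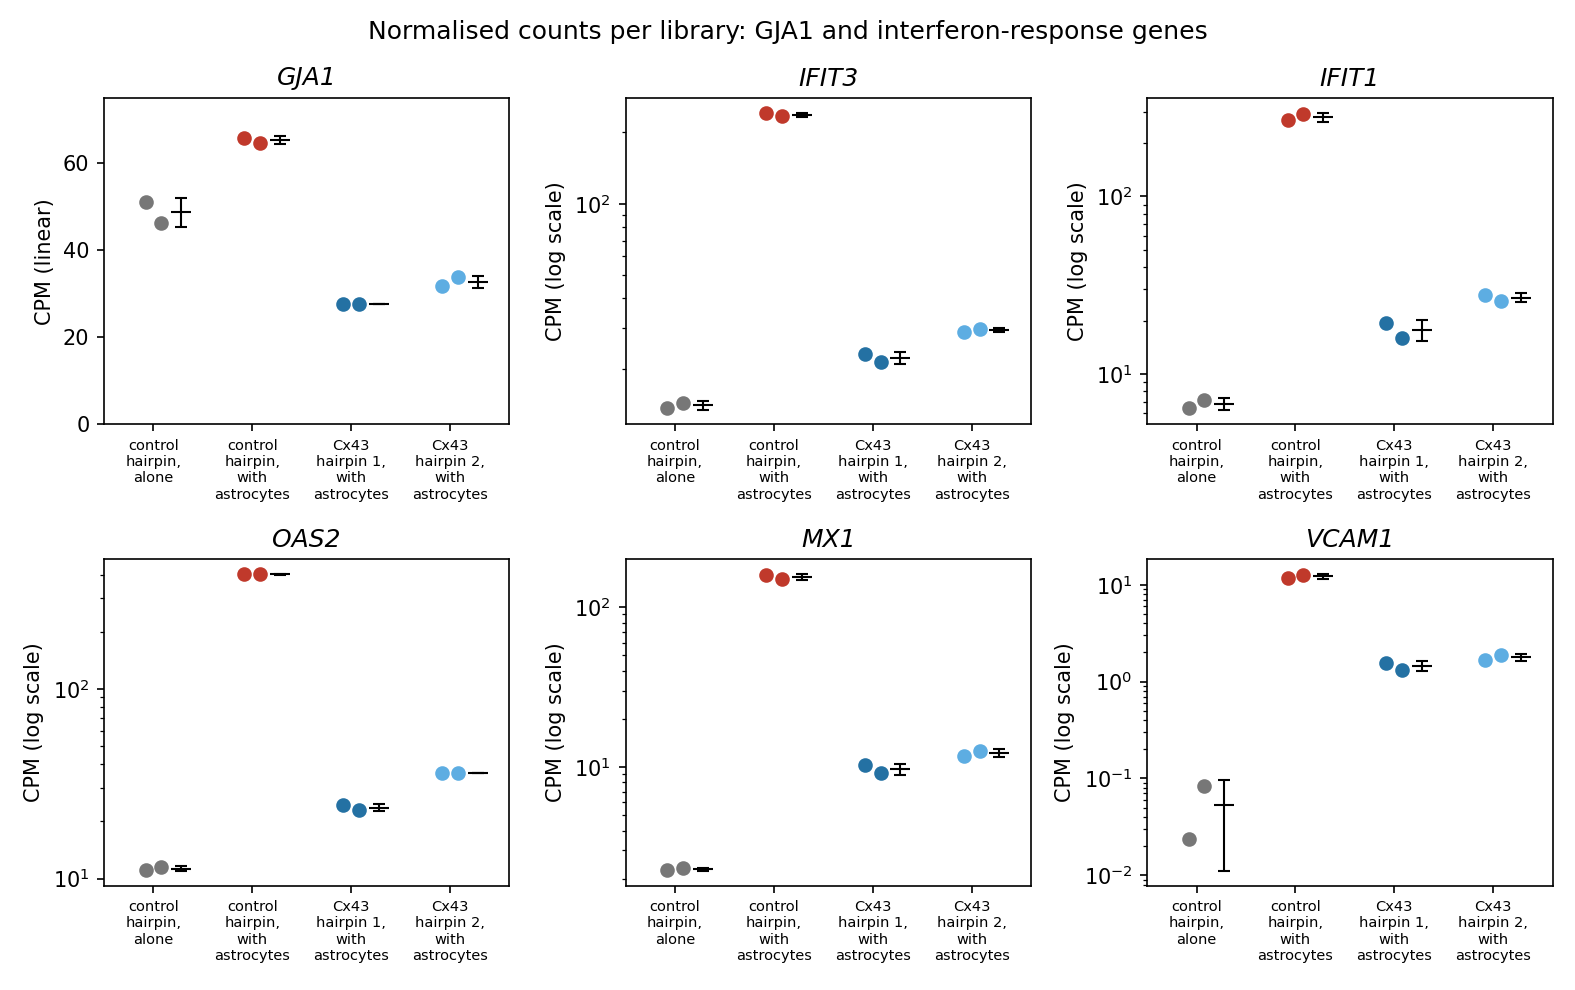
Levels in CPM (vertical axis; linear for GJA1, logarithmic for the other genes) of GJA1, IFIT3, IFIT1, OAS2, MX1 and VCAM1 in the 4 groups, with a point per library and a bar for the mean with its SD (n = 2). IFIT3 averaged 14.1, 238, 22.4 and 29.3 CPM in the groups from left to right, and GJA1 averaged 48.7, 65.3, 27.8 and 32.7 CPM.

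Control cells with and without astrocytes were compared to ask which transcripts on carcinoma cell ribosomes differed in the presence of astrocytes. Interferon-stimulated genes rose almost as a whole list, 49 of 50 tested (49 adjusted over the list alone), with a median of 7.98-fold. The antiviral effectors OAS2, MX1 and IFIT3 rose by 5.15, 6.07 and 4.07 (adjusted p = 4.64e-09, 7.76e-09 and 1.42e-08). OAS2 went from 11.3 ± 0.304 to 401 ± 1.02 CPM and MX1 from 2.29 ± 0.0549 to 154 ± 6.84 CPM. Among the interferon-gamma-inducible genes 18 of 22 rose (20 adjusted over the list alone), including the guanylate-binding protein GBP1 (1.82) and the apolipoproteins L APOL1 (2.09) and APOL6 (1.93).

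Sensors of cytosolic nucleic acid were raised with them. DDX58 and IFIH1 also belong to the interferon-stimulated list, so the tests of these lists are not independent. In the list of cytosolic DNA and RNA sensing 9 of 14 genes rose (10 adjusted over the list alone), among them the RNA sensors DDX58 (2.74) and IFIH1 (4.24), the DNA sensor AIM2 (2.80) and the dNTP hydrolase SAMHD1 (1.91). MB21D1, which encodes the DNA sensor cGAS, did not pass the test (0.21, adjusted p = 0.0996). TMEM173, which encodes the adaptor STING, passed at 0.35 (adjusted p = 0.0248), but not without library 1 (0.36, adjusted p = 0.103) or 2 (0.33, adjusted p = 0.132) of the control cells alone or library 1 of the control coculture (0.28, adjusted p = 0.185). Of 37 TNF and NF-kB targets 25 rose and 1 fell (30 and 1 adjusted over the list alone), with a median of 0.83. These included the adhesion receptor VCAM1 (7.72), the cytokines IL1B (2.38) and LIF (1.04), and the NF-kB regulator BCL3 (1.19). These 4 lists passed the test with the preset correlation and with an estimated correlation, with adjusted p = 6.83e-05 for the interferon-stimulated genes and 0.00139 for each of the others.

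The largest rises were those of CMPK2 (8.21), VCAM1 (7.72), RSAD2 (7.64), IFI44L (6.78), CXCL10 (6.72) and OAS1 (6.71), of which all but VCAM1 and CXCL10 belong to the interferon-stimulated list. Some of these were near the floor in control cells alone. The ratio of reads was 222 for VCAM1 (exact 95% interval 94.6 to 684), 208 for RSAD2 (95.1 to 567) and 110 for CXCL10 (50.1 to 300), the ligand of the chemokine receptor CXCR3. The largest falls were smaller: KRTAP2-3 by 1.51, LY6G5B by 1.45, SPNS2 by 1.28, ANO2 by 1.23, KIF17 by 1.14 and DUSP26 by 1.11. KRTAP2-3 belongs to a family of near-identical keratin-associated genes, among which reads cannot be assigned with certainty. SPNS2, a sphingosine 1-phosphate exporter, and KIF17, a kinesin, kept their calls without each library, as did KRTAP2-3. LY6G5B lost its call without library 1 of the control cells alone (-0.89, adjusted p = 0.169), either control coculture library (adjusted p = 0.168 and 0.13) or either hairpin 2 library (adjusted p = 0.0666 and 0.0665). ANO2 lost it without either library of control cells alone (adjusted p = 0.141 and 0.162) or library 1 of the control coculture (-0.84, adjusted p = 0.275). DUSP26 lost it without library 2 of the control cells alone (adjusted p = 0.0738) or either control coculture library (adjusted p = 0.0772 and 0.0533).

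Further lists passed the preset test but not the test with an estimated correlation. In the antigen processing list 11 of 16 genes rose (12 adjusted over the list alone; adjusted p = 0.0955 with an estimated correlation), including the peptide transporter TAP1 (1.57), the MHC class I transactivator NLRC5 (1.16) and HLA-E (0.52). Of 25 apoptosis and survival genes 10 rose and 1 fell (11 and 1 adjusted over the list alone; adjusted p = 0.0614 with an estimated correlation), among them the death ligand TNFSF10 (3.54), the anti-apoptotic MCL1 (0.81) and the pro-apoptotic BBC3 (1.02). Of 25 immediate-early genes 9 rose (11 and 1 fall adjusted over the list alone; adjusted p = 0.0955 with an estimated correlation), including DUSP1 (0.94), ZFP36 (0.98) and JUNB (0.72). Of 18 p53 targets 8 rose (8 adjusted over the list alone; adjusted p = 0.0925 with an estimated correlation), including BTG2 (1.18) and CDKN1A (0.81). Of 28 TGF-beta targets and EMT genes 12 rose and 2 fell (17 and 3 adjusted over the list alone; adjusted p = 0.193 with an estimated correlation), led by BHLHE40 (1.83), SKIL (0.85) and ID1 (0.90). Of 14 Notch targets 6 rose (6 adjusted over the list alone; adjusted p = 0.194 with an estimated correlation), including the ligands DLL1 (2.40) and JAG1 (0.69).

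Of 16 brain metastasis genes 5 rose and 1 fell (6 and 2 adjusted over the list alone; adjusted p = 0.193 with an estimated correlation): CSF3 (2.62), ANGPTL4 (1.17) and PTGS2 (0.95) were higher and the sialyltransferase ST6GALNAC5 lower (-1.03). PCDH7, a protocadherin, was 0.36 higher without passing the test (adjusted p = 0.0914). Of 9 interferon ligands and receptors 5 rose (6 adjusted over the list alone; adjusted p = 0.248 with an estimated correlation), including the kinase JAK2 (0.54), and the list's call ended without library 1 of the control coculture (mean 0.24, adjusted p = 0.0632). Among G2 and M phase genes the list was called lower, with 1 rise and 3 falls in 30 (1 and 6 adjusted over the list alone; adjusted p = 0.214 with an estimated correlation).

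Markers of other cell types moved in the same comparison. Of 25 tested astrocyte markers 6 rose (8 adjusted over the list alone), including SOX2 (1.12), the glial filament GFAP (0.62) and the glutamate transporter SLC1A3 (0.89). These were already at 8.23, 8.66 and 2.86 CPM in control cells alone, so their rises need not come from astrocyte reads. The astrocyte list did not pass (median 0.12, adjusted p = 0.0502), but did without library 1 of the control cells alone (adjusted p = 0.0287). All 6 tested microglia and macrophage markers rose (6 adjusted over the list alone; adjusted p = 0.0955 with an estimated correlation), including LAPTM5 (0.77) and CD74 (0.58), the MHC class II invariant chain. CD74 is also a member of the interferon-gamma-inducible list, so its rise does not mark microglia alone. Of 8 oligodendrocyte lineage markers 4 rose (5 adjusted over the list alone; adjusted p = 0.45 with an estimated correlation), led by CLDN11 (1.23), and that list's call ended without library 2 of the control cells alone (mean 0.33, adjusted p = 0.112).

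The remaining lists did not pass in this comparison. Counts of rises and falls, over all genes, were 3 and 1 of 9 connexins and pannexins (adjusted p = 0.316), 3 and 1 of 18 protocadherins and cadherins (0.316), 1 and 3 of 20 YAP and TEAD targets (0.316), and 1 and 2 of 16 metallothionein and oxidative stress genes (0.357). They were 6 and 2 of 28 receptor ligands and growth factors (adjusted p = 0.148), 5 and 1 of 20 breast carcinoma line markers (0.353), 5 and 2 of 25 cholesterol synthesis genes (0.0924), and 3 and 1 of 25 fibroblast matrix genes (0.724). Adjusted over the list alone, these were 3 and 1, 3 and 1, 4 and 6, and 1 and 2, then 7 and 2, 5 and 2, 10 and 2, and 4 and 5. Rises alone were seen in hypoxia and glycolysis genes (6 of 27, adjusted p = 0.0565), matrix metalloproteases and invasion genes (4 of 21, 0.165), heat shock proteins (2 of 14, 0.947), neuron markers (2 of 9, 0.131), endothelial markers (1 of 9, 0.333) and mitochondrially encoded genes (3 of 15, 0.0502). Adjusted over the list alone, the rises were 7 with 1 fall, 5, 2, 2, 1 and 6. S phase genes had 2 falls of 26 (adjusted p = 0.0603), which did not hold adjusted over the list alone. The lists of unfolded protein response and ATF4 targets (4 rises and 5 falls of 28, or 5 and 6 adjusted over the list alone, adjusted p = 0.814), replication-dependent histones (0.41), oxidative phosphorylation (0.0924) and cytosolic ribosomal proteins (0.134) did not pass either. The heat shock list had a median below 0 with a mean and test above it, and the unfolded protein response list a median and mean above 0 with a test below it.

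In total 1844 of 15806 tested genes differed between the control coculture and control cells alone, of which 1381 rose and 463 fell, with 314 at least 2-fold higher and 27 at least 2-fold lower. The total was 813 and 858 without library 1 or 2 of the control cells alone, 738 and 1077 without library 1 or 2 of the control coculture, and 1200 and 1205 without library 1 or 2 of hairpin 2. Calls held in the full analysis and without each library in turn for 590 genes, 521 higher and 69 lower, including 47 of the interferon-stimulated genes. Lists whose call appeared without a library were the ribosomal proteins (lower without library 1 of the control cells alone, adjusted p = 0.0108, or library 2 of the control coculture, 8.37e-05) and oxidative phosphorylation genes (lower without the same libraries, 0.0169 and 0.00123). Others were hypoxia genes (higher without library 1 of the control cells alone, adjusted p = 0.0441) and mitochondrially encoded genes (0.0314 without library 1 of the control cells alone, 0.0248 without library 2 of the control coculture, 0.029 and 0.0305 without library 1 or 2 of hairpin 1). The fibroblast matrix list was called lower without library 2 of the control cells alone (mean -0.25, adjusted p = 5.53e-06) and higher without library 1 (mean 0.26, adjusted p = 0.0441).

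Cocultures with Cx43 hairpins were compared with the control coculture to ask which of the transcripts depended on Cx43 in the carcinoma cells. Interferon-stimulated genes fell, 49 of 50 (50 adjusted over the list alone), with a median 4.41-fold lower level. IFIT3 was 22.4 ± 1.29 CPM with hairpin 1 and 29.3 ± 0.611 CPM with hairpin 2, against 238 ± 4.39 CPM in the control coculture (log2 change -3.21, adjusted p = 7.67e-09). OAS2 averaged 23.6 ± 0.991 and 36.0 ± 0.0936 CPM with the hairpins, and MX1 9.70 ± 0.776 and 12.2 ± 0.655 CPM. The largest falls were those of CXCL10 (-4.71), OAS1 (-4.70), MX2 (-4.09), MX1 (-3.82), OAS2 (-3.78) and CXCL11 (-3.78), all antiviral effectors or interferon-induced chemokines. Of 22 interferon-gamma-inducible genes 18 fell (18 adjusted over the list alone), including GBP1 (-1.75) and APOL1 (-1.42).

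The sensing genes, some of them shared with the interferon-stimulated list, and NF-kB targets fell as well. Of 14 sensing genes 8 fell (9 and 1 rise adjusted over the list alone), including DDX58 (-2.27), IFIH1 (-2.80), AIM2 (-1.94) and SAMHD1 (-1.65), while MB21D1 (-0.07, adjusted p = 0.516) and TMEM173 (-0.25, adjusted p = 0.0598) did not pass. Of 37 TNF and NF-kB targets 20 fell (25 and 1 rise adjusted over the list alone), among them VCAM1 (-2.92), the interleukins IL1A (-1.01) and IL1B (-0.93), and the apoptosis inhibitor BIRC3 (-0.47). Of 25 cholesterol synthesis genes 14 fell (20 adjusted over the list alone; median -0.30), including INSIG1 (-0.92), a retention protein of the sterol sensor, and the squalene synthase FDFT1 (-0.46). INSIG1 was 239 ± 0.153 CPM in the control coculture and 129 ± 1.39 and 123 ± 0.601 CPM with the hairpins. With an estimated correlation the adjusted p was 6.5e-06 for the interferon-stimulated genes, 0.00126 for the interferon-gamma-inducible genes, 0.00134 for sensing, 0.00583 for TNF and NF-kB targets and 0.0205 for cholesterol synthesis.

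The largest rises were those of the sialyltransferases ST6GAL2 (1.51) and ST6GALNAC3 (0.88), of LDLRAD4 (1.22), an inhibitor of TGF-beta signalling, of the IGFBP protease PAPPA2 (1.16), of the noncoding RNA MIAT (0.84) and of ZNF66 (0.82). MIAT lost its call without library 1 (adjusted p = 0.0975) or 2 (0.125) of the control coculture or library 1 (0.0637) or 2 (0.0553) of hairpin 2. ZNF66 lost it without the same libraries (adjusted p = 0.154, 0.0935, 0.0782 and 0.0808).

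Other lists were called lower with the preset correlation only. Antigen processing genes fell in 11 of 16 cases (15 adjusted over the list alone; adjusted p = 0.053 with an estimated correlation), including TAP1 (-1.22), HLA-E (-0.60) and the immunoproteasome subunit PSMB8 (-0.76). Immediate-early genes had 12 falls and 1 rise in 25 (14 and 1 adjusted over the list alone; adjusted p = 0.053 with an estimated correlation), with DUSP1 (-0.86), DUSP5 (-0.86) and ZFP36 (-0.66) among them. Apoptosis and survival genes had 7 falls in 25 (9 adjusted over the list alone; adjusted p = 0.0761 with an estimated correlation), including TNFSF10 (-3.05) and BBC3 (-0.55). Heat shock proteins had 7 falls in 14 (10 adjusted over the list alone; adjusted p = 0.144 with an estimated correlation), including HSP90AB1 (-0.53), and hypoxia and glycolysis genes 6 in 27 (12 adjusted over the list alone; adjusted p = 0.141 with an estimated correlation).

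Brain metastasis genes had 5 falls in 16 (6 and 1 rise adjusted over the list alone; adjusted p = 0.287 with an estimated correlation), led by CSF3 (-1.29). PCDH7 did not pass the test (adjusted p = 0.999). G2 and M phase genes had 4 falls in 30 (7 adjusted over the list alone; adjusted p = 0.287 with an estimated correlation), including the phosphatase CDC25C (-0.71) and the spindle protein DLGAP5 (-0.43). Ribosomal protein genes had 3 falls in 53 and oxidative phosphorylation genes 2 in 34 (3 and 1 adjusted over the list alone; adjusted p = 0.647 for each with an estimated correlation).

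Markers of other cell types were again among the genes that moved. Of 20 breast carcinoma line markers 7 fell as well (7 and 3 rises adjusted over the list alone, list adjusted p = 0.0692). Of 25 astrocyte markers 5 fell (5 adjusted over the list alone), including CLU (-0.62) and SOX2 (-0.57), without a call for the list (median -0.17, adjusted p = 0.0982), and GFAP did not pass (0.09, adjusted p = 0.464). Fibroblast matrix genes had 7 falls in 25 (12 and 1 rise adjusted over the list alone; adjusted p = 0.482 with an estimated correlation), including SPARC (-0.51) and FBLN1 (-0.50). Falls in neuron, microglia and oligodendrocyte markers numbered 2 of 9, 3 of 6 and 2 of 8 (3, 3 and 3 adjusted over the list alone; adjusted p = 0.173, 0.285 and 0.615 with an estimated correlation), among them MAP2 (-0.82) and CLDN11 (-0.50).

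Genes of the unfolded protein response and ATF4 list moved both ways, with 8 rises and 8 falls of 28 (9 and 10 adjusted over the list alone; list adjusted p = 0.373). The pseudokinase TRIB3 (0.72), VLDLR (0.54) and SESN2 (0.58) rose and the endoplasmic reticulum chaperone HSPA5 fell (-0.73). The p53 list had 3 rises, including ZMAT3 (0.60), and 3 falls in 18 (3 and 5 adjusted over the list alone; list adjusted p = 0.604). The TGF-beta list had 4 rises and 5 falls in 28 (5 and 8 adjusted over the list alone; list adjusted p = 0.177), with falls of ID1 (-0.81) and BHLHE40 (-0.49). The p53 list had a median and mean below 0 with a test above it, and the Notch list a median above 0 with a mean and test below it.

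Over both hairpins 1457 genes differed from the control coculture, of which 533 rose and 924 fell (830 and 774 with quantile normalization and limma, 786 and 699 scaled by library size only), with 5 at least 2-fold higher and 136 at least 2-fold lower. The total was 448 and 346 without library 1 or 2 of the control coculture, 2311 without library 1 of hairpin 1, and 569 and 433 without library 1 or 2 of hairpin 2. Calls held in the full analysis and without each library in turn for 277 genes, 32 higher and 245 lower, including 47 of the interferon-stimulated genes. List calls that ended without a library were those of brain metastasis genes (library 2 of the control coculture, adjusted p = 0.139, library 2 of hairpin 1, 0.0552, or library 2 of hairpin 2, 0.0566), G2 and M phase genes (library 2 of the control coculture, 0.0576) and ribosomal proteins (library 2 of the control coculture, 0.808, or library 2 of hairpin 1, 0.0632). The same held for oxidative phosphorylation (adjusted p = 0.708 and 0.166 without those libraries), microglia markers (0.0667 without library 2 of the control coculture), neuron markers (0.0505 without library 1 of the control coculture) and oligodendrocyte markers (0.203 without library 1 of the control coculture and 0.107 without library 1 of hairpin 1).

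**Figure D2:**
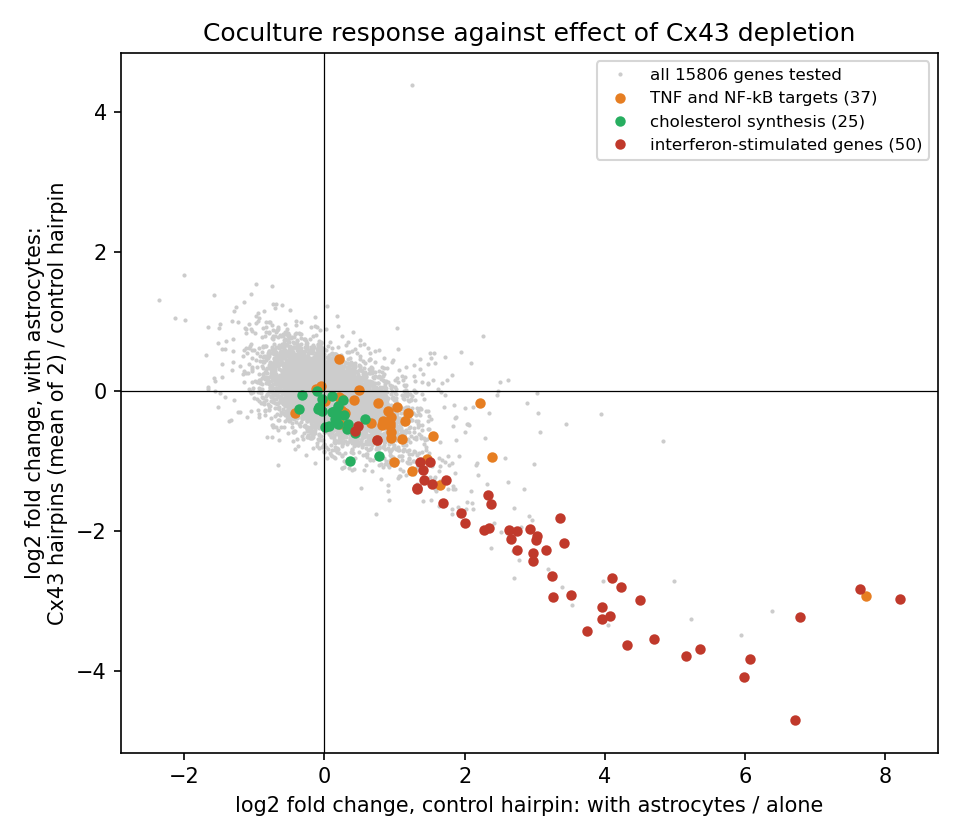
Log2 fold change on coculture of control cells (horizontal axis) against log2 fold change on Cx43 depletion in coculture (vertical axis), a point per gene, with all 15806 tested genes in grey, 50 interferon-stimulated genes in red, 37 TNF and NF-kB targets in orange and 25 cholesterol synthesis genes in green. Interferon-stimulated genes lie at the lower right, with medians of 2.997 and -2.14, and both axes share the control coculture libraries.

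Each hairpin was also compared with the control coculture on its own. With hairpin 1 there were 1236 calls (488 higher and 748 lower). These were 721 and 625 with quantile normalization and limma, and 826 and 586 scaled by library size only. With hairpin 2 there were 658 (152 higher, 506 lower). With only the compared groups in the fit, hairpin 1 had 233 calls and hairpin 2 had 980, so their order turned. Interferon-stimulated genes fell in 49 of 50 cases with each, with medians of -2.23 and -2.07 (adjusted p = 1.01e-05 and 1.4e-05 with an estimated correlation). Falls numbered 18 and 16 of 22 interferon-gamma-inducible genes, 7 and 7 of 14 sensing genes, 20 and 9 of 37 TNF and NF-kB targets, and 11 and 10 of 25 cholesterol synthesis genes. Adjusted over the list alone, falls numbered 50 and 50 interferon-stimulated genes, 19 and 18, 10 and 9 with 1 rise each, 25 with 1 rise and 19, and 17 and 20. With hairpins 1 and 2 the largest falls were those of OAS1 (-5.07 and -4.32), CXCL10 (-5.0025 and -4.41), MX2 (-4.18 and -3.99), MX1 (-3.99 and -3.66) and OAS2 (-4.09 and -3.48). CXCL11 with hairpin 1 (-4.20) and OASL with hairpin 2 (-3.40) completed the 6 largest falls. Among the largest rises PAPPA2 (1.06 and 1.26), ST6GAL2 (1.66 and 1.37) and LDLRAD4 (1.38 and 1.06) were called with both. With hairpin 2 the call of ST6GAL2 ended without library 1 or 2 of the control coculture (adjusted p = 0.0859 and 0.0604) or of hairpin 2 (0.0692 and 0.111), and that of LDLRAD4 without library 1 or 2 of hairpin 2 (0.0509 and 0.0685).

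With hairpin 1 alone the ribosomal protein and oxidative phosphorylation lists were called lower, with falls in 6 of 53 and 2 of 34 genes (21 and 5 adjusted over the list alone; medians -0.36 and -0.29; adjusted p = 0.594 for each with an estimated correlation). With hairpin 2 their medians were -0.08 and -0.09, without a call, but without library 1 of the control coculture both were called lower (means -0.24 and -0.20, adjusted p = 3.64e-05 and 0.00621), and without library 2 the ribosomal list was called higher (mean 0.13, adjusted p = 0.0313). The difference between hairpins passed for both lists at the preset correlation (medians 0.29 and 0.22, adjusted p = 9.3e-21 and 7.7e-10) but not with an estimated correlation (adjusted p = 0.464 for each). That difference ended for oxidative phosphorylation without library 2 of hairpin 1 (adjusted p = 0.0958). The oxidative phosphorylation call with hairpin 1 ended without library 2 of the control coculture (adjusted p = 0.0639) or of hairpin 1 (0.0786). Across 13235 genes the log2 change correlated with transcript length at a rho of 0.36 for hairpin 1, 0.09 for hairpin 2 and -0.44 for the difference of hairpin 2 from hairpin 1. For the coculture of control cells the rho was 0.21, and for depletion 0.26.

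The remaining rises in the lists of 6 were ST6GALNAC3 (0.99), HSPA6 (1.28) and SYT12 (0.90) with hairpin 2, and SHISA9 (1.34), MIAT (0.97) and DACT1 (0.88) with hairpin 1. Apart from ST6GALNAC3 these calls ended without some libraries. HSPA6, a heat shock protein, lost its call without library 1 of the control coculture (adjusted p = 0.0677) or of hairpin 2 (0.0815), and SYT12 without library 1 or 2 of the control coculture (0.0775 and 0.148) or of hairpin 2 (0.178 and 0.148). MIAT lost it without library 1 or 2 of the control coculture (adjusted p = 0.0767 and 0.117) or library 2 of hairpin 1 (0.0662), and DACT1 without those (0.0965, 0.086 and 0.0834) or library 1 or 2 of hairpin 2 (0.0533 and 0.0524). SHISA9 kept its call only in the full analysis and without library 1 of hairpin 1, with adjusted p from 0.0639 to 0.215 without any other library.

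Both hairpins called 542 genes in the same direction, 128 higher (4.69 if the lists were independent) and 414 lower (23.9 if independent), and no gene in opposite directions. In 20 simulations of unchanged groups that shared the control libraries, the correlation of log2 changes across genes was 0.52, against 0.78 in the data, and 67.0% of genes had the same sign with both hairpins, against 77.5% (genes are not independent replicates). The simulations drew each gene independently, so they hold no deviation shared across genes, such as a trend with transcript length between replicates. They are therefore not a full null for these libraries. Depletion calls in the simulations averaged 0.3 genes, so they give no value to set beside the 542. The controls could not be divided into separate sets of 2, so part of the excess may come from shared control libraries. The total was 210 and 191 without library 1 or 2 of the control coculture and 153 and 143 without library 1 or 2 of hairpin 2, and 5 higher and 118 lower genes were called by both hairpins without each library in turn. The hairpin 1 total was 758 without either library of control cells alone, 424 and 281 without library 1 or 2 of the control coculture, 2407 and 573 without library 1 or 2 of hairpin 1, and 469 without either library of hairpin 2. The hairpin 2 total was 243 and 237 without library 1 or 2 of the control coculture, 1096 and 1097 without library 1 or 2 of hairpin 1, and 157 and 150 without library 1 or 2 of hairpin 2.

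The difference between the hairpins was tested directly. By edgeR 5 genes passed, 4 higher and 1 lower with hairpin 2, against 1084 at an unadjusted p under 0.05 and 22 by DESeq2. OAS2 (0.61), IL1B (1.15), RPN1 (0.52), a subunit of the oligosaccharyltransferase, and HSPA6 (1.66) were higher with hairpin 2. IL1B lost its call without library 1 or 2 of hairpin 2 (adjusted p = 0.188 and 0.0668). OAS2 (adjusted p from 0.0737 to 0.881), RPN1 (0.0902 to 0.982) and HSPA6 (0.0859 to 0.881) lost theirs without any single library. The total was 2 without any 1 control library, 3 without either hairpin 1 library, 0 without library 1 of hairpin 2 and 1 without library 2 of hairpin 2. Interferon-stimulated genes were 0.25 higher with hairpin 2 by the median, with 1 of 50 called (16 adjusted over the list alone; adjusted p = 0.0166 with an estimated correlation), and TNF and NF-kB targets 0.15 higher, with 1 of 37 called (7 adjusted over the list alone; adjusted p = 0.0229 with an estimated correlation). At the preset correlation 15 of the 35 lists were called, and 7 without library 2 of hairpin 1.

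The genes that changed with astrocytes were then followed into the depleted cocultures. Of 1381 genes raised in the control coculture 532 were lower on depletion, where 80.7 would be shared by independent lists, and of 463 lowered genes 91 were higher on depletion, where 15.6 would be shared. The comparisons share the control coculture libraries with opposite sign, which raises such overlaps, and the simulations, which called a mean of 0.3 genes on depletion, could not say by how much. Over all tested genes the log2 changes correlated at -0.64, against -0.60 in the simulations, and had a covariance of -0.0922, against -0.0218. The share of genes with opposite signs was 63.0%, below the 69.9% of the simulations (69.4% to 70.5%). As the simulations drew each gene independently, their values leave out deviations shared across genes. Reversal was called without each library in turn for 188 raised and 2 lowered genes. The total of 623 reversed genes was 373 and 349 without library 1 or 2 of the control cells alone, 253 and 250 without library 1 or 2 of the control coculture, and 339 and 304 without library 1 or 2 of hairpin 2.

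Depleted cocultures were last compared with control cells alone, a comparison added after the data were seen in which no library of the control coculture was contrasted. Of 50 interferon-stimulated genes 37 were higher than in control cells alone (38 adjusted over the list alone), with a median of 0.68 (adjusted p = 0.00578 with an estimated correlation). OAS2 was 1.37 higher, MX1 2.25 and CMPK2 5.25 (adjusted p = 1.36e-05 for each). IL1B (1.45), LIF (0.82) and BCL3 (0.89) were among the 17 higher and 2 lower of 37 TNF and NF-kB targets (22 and 2 adjusted over the list alone; adjusted p = 0.0185 with an estimated correlation). The p53 targets TP53INP1 (1.11), BTG2 (1.16) and CDKN1A (0.50) were among 9 higher and 1 lower of 18 (10 and 1 adjusted over the list alone; adjusted p = 0.0348 with an estimated correlation). Of 30 G2 and M phase genes 16 were lower (26 adjusted over the list alone; adjusted p = 0.0468 with an estimated correlation), including CCNB1 (-0.57) and CDC20 (-0.47). PCDH7 was called higher (0.36, adjusted p = 0.0467), but not without library 1 or 2 of the control cells alone (0.141 and 0.23), library 2 of hairpin 1 (0.0705) or library 1 or 2 of hairpin 2 (0.126 and 0.0973), nor with quantile normalization and limma (0.0712) or the replicate block (0.088). In the same comparison log2 changes followed transcript length with a rho of 0.41 across 13235 genes. Fibroblast matrix genes were called lower (12 falls and 1 rise of 25, 15 and 2 adjusted over the list alone; adjusted p = 6.33e-05, and 0.395 with an estimated correlation), though not without library 1 of the control cells alone (0.0668). Ribosomal protein genes (7 of 53, 7 adjusted over the list alone) and oxidative phosphorylation genes (8 of 34, 12 adjusted over the list alone) were also called lower (adjusted p = 2.52e-08 and 4.12e-07, and 0.622 and 0.56 with an estimated correlation). Microglia markers were called higher (3 of 6, 3 adjusted over the list alone; adjusted p = 0.00756, and 0.199 with an estimated correlation), though not without library 1 of the control cells alone (0.0617) or of hairpin 1 (0.0568). Cholesterol synthesis genes were called lower as well (9 of 25, 12 adjusted over the list alone; adjusted p = 1.31e-05, and 0.0546 with an estimated correlation). The part of the log2 rise kept in depleted cocultures was computed only for list members called higher in the control coculture. Its median was 24.5% for interferon-stimulated genes (n = 49), 52.4% for TNF and NF-kB targets (n = 25) and 95.4% for p53 targets (n = 8). The median was 113% for TGF-beta targets and EMT genes (n = 12). It was -35.1% for the cholesterol synthesis genes so picked (n = 5), below control cells alone, from a list not called on coculture (adjusted p = 0.0924). All of these percentages rest on the same control libraries, and differences between them were not tested. The members were picked by the rise that the percentages are taken of, which can bias the part kept.

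In that comparison RSAD2 (4.82), VCAM1 (4.80), the chemokine CXCL6 (4.13), the bradykinin receptor BDKRB2 (3.62) and IFI44L (3.55) completed the 6 largest rises with CMPK2. The largest falls were those of KRTAP2-3 (-1.74), ANO2 (-1.52), PABPC1L (-1.52), SPNS2 (-1.41), RGS4 (-1.40) and ID3 (-1.26). ANO2 lost its call without library 1 or 2 of the control cells alone (adjusted p = 0.0672 and 0.0679). PABPC1L lost it without library 1 of the control cells alone (-0.57, adjusted p = 0.061) or library 1 or 2 of hairpin 2 (0.0651 and 0.074). In total 2709 genes differed, 1707 higher and 1002 lower. The total was 573 and 787 without library 1 or 2 of the control cells alone, 4723 without library 1 of hairpin 1, and 1285 and 831 without library 1 or 2 of hairpin 2.

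**Figure D3:**
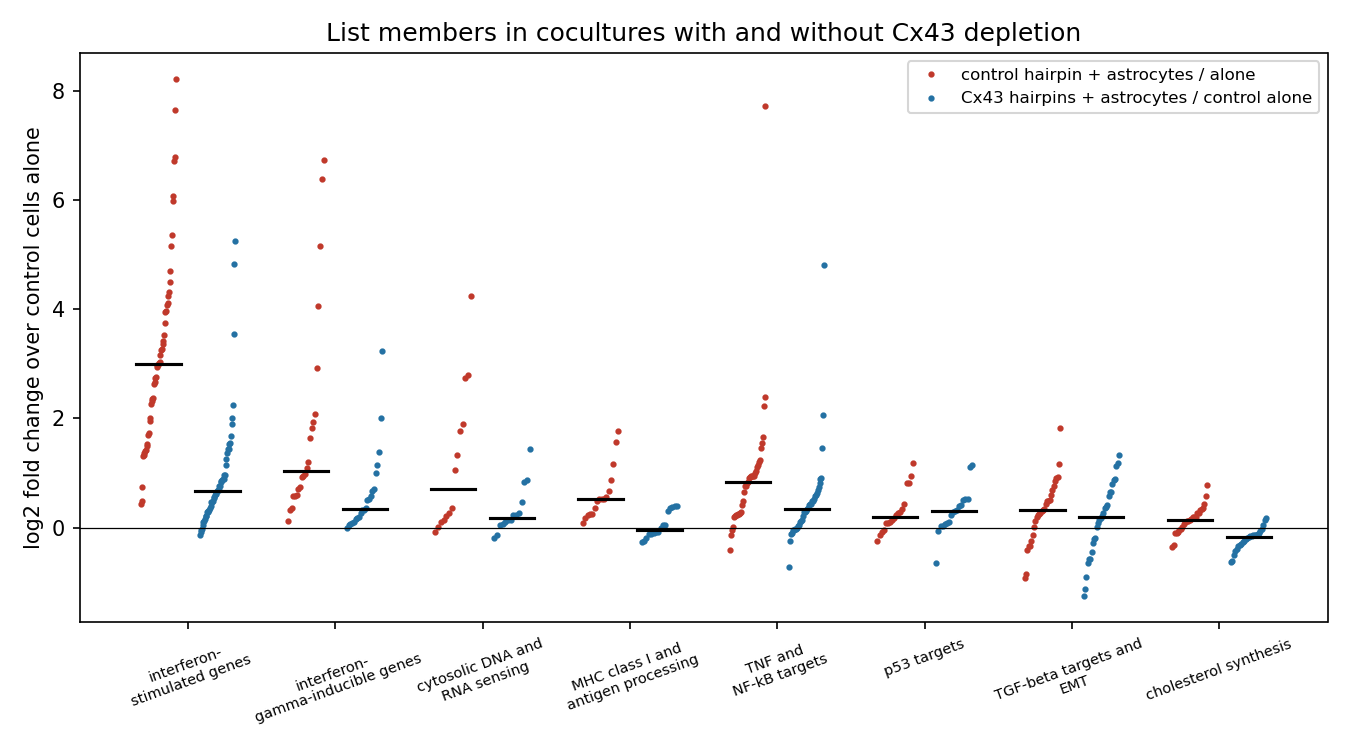
Log2 fold change against control cells alone (vertical axis) of the tested members of 8 gene lists (horizontal axis), a point per gene, for the control coculture in red and the mean of the Cx43-depleted cocultures in blue, with black bars at the medians. Interferon-stimulated genes have medians of 2.997 and 0.68, and TNF and NF-kB targets of 0.83 and 0.34.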

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

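The test of a single library below was chosen only after the result was seen, while the transcript length test was set out before its result was seen. The 6 results in this part stood out because hairpin 2 and hairpin 1 differed from each other by the test of their difference.

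The level of IL1B, a cytokine gene, was 6.66 CPM with hairpin 1 and 14.8 CPM with hairpin 2 (log2 difference 1.15, adjusted p = 0.00678). OAS2 was 0.61 higher with hairpin 2 (adjusted p = 0.04). RPN1 was 140 and 201 CPM (0.52, adjusted p = 0.0461), and HSPA6 was 0.757 and 2.39 CPM (1.66, adjusted p = 0.0461). IL1B lost its call without library 1 or 2 of hairpin 2 (adjusted p = 0.188 and 0.0668). OAS2, RPN1 and HSPA6 lost theirs without any single library, with adjusted p from 0.0737, 0.0902 and 0.0859 up to 0.881, 0.982 and 0.881. With the replicate block none of these 4 genes was called. With only the compared groups OAS2, RPN1 and HSPA6 were not called, HSPA6 was not called by limma with any pseudocount, and RPN1 and HSPA6 were not called with the filter at 50, with quantile normalization and limma or with library size only. The interferon-stimulated list differed by a median of 0.25 and the TNF and NF-kB list by a median of 0.15, so both were less reduced with hairpin 2. Between the hairpins log2 differences followed transcript length with a rho of -0.44 across genes, and the ribosomal protein and oxidative phosphorylation lists were higher by medians of 0.29 and 0.22 (adjusted p = 9.3e-21 and 7.7e-10 at the preset correlation, 0.464 for each with an estimated correlation), the latter not without library 2 of hairpin 1 (0.0958). The groups of 2 are too small for a test of single libraries far from the rest of their group.

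Ribosomal protein and oxidative phosphorylation genes were lower with hairpin 1, with a median log2 change of -0.34 over 87 genes. The log2 ratio of library 1 over library 2 followed transcript length in every group, with a rho of -0.54 across genes for hairpin 1. The rho was 0.32 in control cells alone, 0.49 in control cocultures and -0.42 for hairpin 2. After the trend of the hairpin 1 change with length was removed the median was -0.12 (quartiles -0.24 and -0.05). A difference in the recovery of short and long transcripts may therefore account for most of the change. Without library 2 of hairpin 1 the median was -0.18, against -0.54 without library 1, and with 2 libraries it cannot be told apart which of them departs from the group. No biological explanation was tested beyond the hairpin itself, which remains open for the part that is left.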

How the results depend on the processing

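Changes were made to 1 choice at a time, except that quantile normalization and the pseudocounts were run with limma and that DESeq2 brought its own size factors with its own test. The alternatives limma with a pseudocount of 1, median-of-ratios factors, library size only and the crossed block, as well as all values of the comparison of depleted cocultures with control cells alone, were chosen after the data were seen. The edgeR test and TMM factors, planned as alternatives for normalized values, became the reported analysis. The GJA1 fall with either hairpin kept its direction and call in each alternative run. Over all alternatives the calls of single genes other than GJA1 were the same in 17396 cases, weaker in 1403, stronger in 396 and reversed in 1, and those of lists the same in 4254, weaker in 188, stronger in 176 and reversed in 2. For GJA1 they were the same in 124 cases and weaker in 2. Cases called in neither analysis count as the same, so these numbers are not shares of calls kept. They also take in list members that are not named here. No gene called in the reported analysis was called in the opposite direction in any alternative. Genes near the floor in control cells alone, such as VCAM1, have rises whose size the depth limits. Except where fewer genes or a stricter threshold are named, the cause was not tested.

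Without a filter the calls numbered 2805 for coculture, 2269 for hairpin 1, 1191 for hairpin 2, 304 between hairpins, 4117 for depleted cocultures against control cells alone and 874 with both hairpins, and 24 lists were called for coculture. With a fold minimum of 1.5 there were 790 for coculture, 374 for hairpin 1, 274 for hairpin 2, 341 for depletion, 621 for depleted cocultures against control cells alone, 225 with both hairpins and 236 opposed between coculture and depletion. With only the compared groups there were 233 for hairpin 1, 225 with both hairpins and 2 between hairpins. For hairpin 2 there were 980, from as many libraries as for hairpin 1, so fewer libraries alone do not account for these changes. Between hairpins there were also 3 with a filter at 50, 3 with quantile normalization and limma, 3 with library size only and 22 with DESeq2.

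With a replicate block there were 1160 calls for coculture, 446 for hairpin 1, 319 for hairpin 2, 700 for depletion, 0 between hairpins, 1502 for depleted cocultures against control cells alone, 258 with both hairpins and 377 opposed. Equal replicate numbers did not go with a common deviation in all groups: deviations of equal-numbered replicates correlated across genes from -0.56 to 0.32 between groups. The labels do not say whether the numbers mark a pairing, which can be neither shown nor excluded here. With the crossed replicate block, in which the numbers of the Cx43 hairpin groups were exchanged, the same counts were 4174, 3895, 2329, 3721, 361, 5861, 1747 and 1445. This exchange goes with the signs of those deviations, which were positive between control groups and between hairpin groups and negative otherwise. Such a block takes up spread between replicates by construction, so the higher counts lend the calls no support.

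With an estimated correlation 4 lists were called for coculture, 5 each for hairpin 1, hairpin 2, depletion and depleted cocultures against control cells alone, and 2 between hairpins, where the preset gave 15, 17, 17, 18, 16 and 15 in that order. With fry 23 were called for coculture and 3 between hairpins.

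Leaving out each library in turn gave 738 to 2589 calls for coculture, 281 to 2407 for hairpin 1, 150 to 1097 for hairpin 2, 346 to 2311 for depletion, 0 to 3 between hairpins, 573 to 4723 for depleted cocultures against control cells alone, 143 to 730 with both hairpins and 250 to 805 opposed. Called lists ranged from 7 to 16 between hairpins. The GJA1 rise on coculture ranged from 0.34 to 0.48. Without library 1 of the control cells alone COL3A1 was 0.85 higher on coculture (-0.08 with it) and the fibroblast matrix list was called higher (mean 0.26). The lowest values, without library 2, were -0.67 and -0.25. Without library 2 of the control coculture the ribosomal protein list was called higher with hairpin 2 (mean 0.13), and without library 1 it was called lower (-0.24, the lowest value).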

Other observations

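Of the tests of explanations in this part, only the removal of length trends from the interferon-stimulated genes was set out before its result was seen. The other tests of explanations, with the genes named here, were chosen after their results were seen.

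Some chemokine genes stayed well above their level in control cells alone when Cx43 was depleted. The neutrophil chemokine genes CXCL5 and CXCL6 were 2.39 ± 0.172 and 0.384 ± 0.0453 CPM in control cells alone, 25.9 ± 1.53 and 11.1 ± 1.77 CPM in control cocultures (n = 2 each), and 18.8 ± 1.71 and 6.81 ± 0.815 CPM in depleted cocultures (n = 4). Their falls on depletion (-0.46, adjusted p = 0.0085, and -0.70, adjusted p = 0.0109) were not called without library 2 of the control coculture (adjusted p = 0.111 and 0.131) or of hairpin 2 (0.051 and 0.0596). The monocyte chemokine gene CCL2 rose by 2.23 on coculture and did not pass on depletion (-0.17, adjusted p = 0.478). Between depleted cocultures and control cells alone CXCL5, CXCL6 and CCL2 differed by 2.98, 4.13 and 2.06. CXCL10, which rose by 6.72 and changed by -4.71 on depletion, still differed by 2.01, which did not pass (adjusted p = 0.0536). It passed in 12 of 21 alternatives, but these refit the same libraries and lend no independent support. CXCL10 had only 6 reads in all in control cells alone.

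Both coculture and depletion raised 16 genes and lowered 4, where 46.6 and 27.1 would be shared by independent lists. The control coculture libraries, shared with opposite sign, lower both numbers by construction. The 4 lowered genes were RGS4 (-0.75 and -0.65), which kept both calls without each library, and C4BPB (-0.62 and -0.51), SPOCD1 (-0.32 and -0.28) and LINC00707 (-0.34 and -0.25), whose calls ended without some libraries in both comparisons (adjusted p up to 0.153, 0.195 and 0.0738 on coculture and 0.234, 0.26 and 0.195 on depletion). CDKN2B, a cyclin-dependent kinase inhibitor, rose by 0.51 in each comparison and kept both calls without each library. SKIL, a corepressor of SMAD proteins, rose by 0.85 and 0.34, the latter call ending without library 1 or 2 of the control coculture (adjusted p = 0.124 and 0.111) or of hairpin 2 (0.0628 and 0.0998). SMAD7, an inhibitory SMAD, rose by 0.44 and 0.35, with calls that ended without some libraries in both comparisons (adjusted p = 0.0767 without library 2 of the control cells alone and 0.09 without library 1 of the control coculture for the former, and 0.071 to 0.151 without a control coculture or hairpin 2 library for the latter). On depletion the stress-response genes CHAC1 (0.62) and ADM2 (0.64) rose with TRIB3 (0.72), while the chaperone gene HSPA5 changed by -0.73. The transcript CTD-2328D6.1 was 57.9, 66.1 and 58.4 CPM in 3 of the 4 depleted libraries and 1.64 CPM in library 1 of hairpin 1, and its depletion change did not pass (4.38, adjusted p = 0.0535).

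The rise of interferon-stimulated genes with astrocytes and their fall on Cx43 depletion could in part reflect astrocyte RNA carried through the pull-down. A smaller share of astrocyte RNA in the depleted cocultures is argued against as the whole cause only if the rises of astrocyte markers came from astrocyte reads, which was not tested: the 6 astrocyte markers that rose kept a median of 45.5% of their rise in CPM (quartiles 38.9% and 94.0%, range 31.8% to 123%), while 49 interferon-stimulated genes kept 6.88% (4.95% and 12.3%, highest 21.9%). As part of the cause it stays open, since SOX9, SLC1A3, SOX2 and GPM6B kept only 31.8% to 51.4%, against 108% for NTRK2 and 123% for GFAP. On depletion 5 of 25 astrocyte markers fell and 0 rose, but 7 of 20 breast carcinoma line markers also fell and 0 rose. Falls were therefore not particular to astrocyte markers. A trend with transcript length is also argued against, since the median change on depletion was -2.15 after its removal and -2.14 before. A constant share of RNA from astrocytes whose own interferon-stimulated genes differed cannot be told apart from a response in the carcinoma cells, because no astrocyte library was used here: the 25 of 35 listed astrocyte markers with enough counts to be tested in this line rose by 28.1 CPM in all and the interferon-stimulated genes by 4929 CPM. The species of the astrocytes is not stated, and if they were murine only reads that also map to hg19 would be counted, to an extent that differs between genes, so these sums do not measure the share of astrocyte RNA. A Cx43-dependent response of the carcinoma cells, the biological difference in the design, stays open, as does a difference of the depleted cells that is present without astrocytes.

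In library 1 of the control cells alone 18 genes were over 2-fold higher than in library 2, among them FN1 (2.86-fold), COL3A1 (2.67-fold) and DYNC1H1 (2.62-fold). The 15 with a coding transcript had a median length of 9.79 kb, against 3.49 kb for all coding genes tested. These genes were picked by this ratio, so explanations were tested on the matrix list. Some of its longer members, including FN1 and COL3A1, were themselves among the picked genes, so the list is not free of that choice. Its 15 members of 4 kb or more had a median log2 ratio of 0.71, and 0.67 after removal of the length trend (quartiles 0.31 and 0.92), a spread too wide to exclude that trend, which stays open. RNA from fibroblasts as the whole cause is argued against by the 10 matrix genes under 4 kb, whose median log2 ratio was 0.020 (upper quartile 0.36). These ratios were not corrected for the length trend, so a part from fibroblasts cannot be told apart from that trend. No biological explanation was tested, since both libraries belong to the same group. FN1 illustrates the effect on the comparison with astrocytes, with a log2 change of -0.84 with both libraries and 0.09 without library 1.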
